A study of Homo sapiens with 6 samples.

How the data were processed

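RNA from 6 libraries of Cal33, an established human oral squamous cell carcinoma line, was analysed. Per the labels' protocols, cells were transduced with lentivirus made in 293FT cells, a human embryonic kidney line used to package virus, and carried either the empty vector (Vector, 3 libraries) or the vector with FLAG-tagged carboxylesterase 2 (CES2, 3 libraries), under selection with 0.5 ug/ml puromycin. The same protocols describe ribosomal RNA removal and strand-specific libraries. Nothing in the labels says that the 3 libraries of a group came from separate transductions or cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical.

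The deposited values are TPM (transcript abundance scaled to a total of 1000000 per library) for 14136 gene entries in each library, as one table of the whole series. Its header gives no unit, and TPM was inferred from the values: each column summed to between 999804 and 999893. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.3 and edgeR 3.0.8 and the human builds hg38 and GRCh38, without saying which step each served. The annotation, the filters and the handling of strand in counting are not given in the sources used here. Of the entries, 99.9% were protein-coding in GENCODE release 29, and none lay on the mitochondrial chromosome. Coordinates are those of GRCh38 in the deposited table, and 99.3% of the listed transcripts had the same coordinates in GENCODE release 29. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval can be given. A change in a few abundant transcripts also shifts the TPM of all others, because each library is scaled to the same total. The table held no zeros, and 607 entries were blank in at least 1 library. Blanks were read as 0. A set of 20 symbols that had been turned into dates was restored from the gene identifiers, and 10 symbols that stood on more than 1 entry were left out of the naming rule.

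Group membership was taken from the sample labels. Genes with at least 1 TPM in at least 3 libraries were kept (12210 genes), values were transformed as log2(TPM + 1), and CES2 was compared with Vector by limma 3.58.1 in R 4.3.3 with an intensity trend and empirical Bayes moderation, with group as the only term. The Benjamini-Hochberg adjusted p threshold was 0.05. Fold changes are differences on the log2(TPM + 1) scale, which understates the change of low genes, and errors of fold changes are standard errors. The CES2 values were also compared by a two-sided exact permutation test. Before the data were examined, 40 gene lists were fixed from general knowledge of the cell type and the enzyme. The lists with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01. They were compared again by camera with an estimated correlation. With the preset correlation the members count as nearly independent genes. That p-value therefore reflects the number and spread of genes more than the spread between libraries. The fry test, which asks whether the members of a list move on balance one way and compares them with no other genes, was run beside these, with adjustment over the lists tested in each case. Members were also adjusted over the list alone, which does not correct for the number of lists. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for reading and plotting.

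Named genes followed a rule also fixed before the data were examined: CES2 and the other tested carboxylesterase list members, up to 10 genes in each direction past the threshold with non-overlapping groups and a mean of at least 1 TPM in the higher group, and up to 4 members with the smallest unadjusted p of each list that passed or is described. Genes outside this rule are said to be so where they appear.

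The test was tried on simulated data for the same 12210 genes with 200 changed genes at once, drawn from those with higher means. So many changed genes loosen the Benjamini-Hochberg cut. The shares recovered therefore overstate what would be found where few genes change. A gene that did not pass is not shown to be unchanged. When simulated genes varied independently, 36.1% of 2-fold and 95.7% of 4-fold changes were recovered. When simulated genes kept the residual correlation of the real libraries, 32.5% of 2-fold, 83.5% of 4-fold and 94.1% of 8-fold changes were recovered. With no gene changed, camera with the preset correlation passed a median of 0 lists (highest 1) for independent genes but a median of 11 (highest 17) with the real residual correlation.

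Alternatives covered each library left out in turn, the replicate number as a block, median rescaling, quantile normalization, filters on low values, pseudocounts of 0.1 and 0.01, limma without the trend, other thresholds, library weights, other list tests and a list without CES2. Alternatives that need counts do not apply to TPM and were not run. A fit with the first residual component as a covariate, a fit without Vector 1 and CES2 2, and blanks read as missing were added after seeing the data.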

Results

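The transcriptome of Cal33 oral squamous carcinoma cells stably carrying an empty lentiviral vector (Vector, n = 3) was compared with that of cells carrying FLAG-tagged CES2 (CES2, n = 3). CES2 encodes carboxylesterase 2, a serine hydrolase of the endoplasmic reticulum that cleaves ester bonds in drugs and lipids. Abundance was measured as TPM for 14136 gene entries, of which 12210 were tested. Between 73 and 279 entries were blank in a library, and sequencing depth is unknown because TPM does not retain it. Pearson correlations of log2(TPM + 1) were 0.932 to 0.974 between libraries of one group and 0.927 to 0.978 between libraries of different groups.

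The comparison first asks whether the CES2 transcript was raised in the cells given the CES2 construct. CES2 (ENSG00000172831, a gene with 12 exons in the listed transcript of 3868 bases on chromosome 16 from 66934444 to 66945069, plus strand, GRCh38) was at 45.6, 41.9 and 44.9 TPM in Vector and at 2664, 1929 and 2294 TPM in CES2. The means were 44.1 ± 1.96 TPM (SD, n = 3) and 2296 ± 368 TPM (SD, n = 3), and the log2 fold change was 5.66 with a standard error of 0.18 (limma, adjusted p = 7.38e-06). The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. TPM per gene does not separate transcripts of the construct from those of the endogenous gene. The other tested carboxylesterase list members did not pass: log2 fold changes were 0.17 for CES4A, its neighbour on chromosome 16, 0.13 for PON2, -0.16 for ESD and -0.05 for CMBL. The sign of CMBL turned positive under median rescaling and quantile normalization, and that of CES4A turned negative with library weights. The list as a whole was higher (5 tested, 3 higher, camera adjusted p = 2.63e-05, adjusted p = 0.297 with an estimated correlation). That result rested on CES2, since the mean log2 fold change was 1.15 with CES2 and 0.02 without it (adjusted p = 0.654).

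CES2 was the only gene past the threshold among 12210 tested by limma: 1 gene was higher and 0 were lower. At an unadjusted p under 0.05 there were 133 genes, 72 higher and 61 lower, where 610.5 would be expected by chance. That number was 90 without CES2 1, 246 without Vector 2, 256 without CES2 3 and 340 with the first residual component as a covariate, all below the chance number. Only with library weights, which gave CES2 1 a weight of 6.86, was it above that number, at 621. The median log2 fold change of all tested genes was -0.057, and -0.003 after median rescaling. The second smallest adjusted p was 0.451, for CCL2. Groups did not overlap for 131 genes higher and 321 genes lower in CES2, together 3.7% of genes against 10% by chance. The median standard error of a log2 fold change was 0.26. With library weights 4 genes were higher (CES2, CCL2, CXCL1 and CXCL3), and without Vector 1 and CES2 2 there were 2 (CES2 and S100A8).

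Inflammatory genes under NF-kappaB control were the list with the largest difference. Of 28 tested members, 26 were higher in CES2, with a median log2 fold change of 0.98 (camera adjusted p = 1.1e-52, adjusted p = 0.131 with an estimated correlation). None of the members passed over all genes, and 10 passed adjusted over the list alone. That adjustment does not cover the choice of this list among the 36 tested. CCL2, a monocyte chemokine, was at 2.0 ± 1.46 TPM in Vector and 18.1 ± 4.97 TPM in CES2 (SD, n = 3 each), a log2 fold change of 2.74 with a standard error of 0.38 (adjusted p = 0.00207 over the list alone). The neutrophil chemokines CXCL3 and CXCL1 had means of 7.17 and 155 TPM in Vector and 42.0 and 444 TPM in CES2, with log2 fold changes of 2.39 and 1.52 (both adjusted p = 0.00227 over the list alone). TNFAIP3, which encodes the NF-kappaB inhibitor A20, was at 19.2 ± 7.91 TPM and 49.5 ± 9.60 TPM, a log2 fold change of 1.39 (adjusted p = 0.0155 over the list alone). The other members past the threshold over the list alone, named after their values were seen, were CCL20 (log2 fold change 3.39), CXCL2 (1.88), LIF (1.14), IL1A (0.98), NFKBIA (0.89) and RELB (0.75). In the 10 genes past over the list alone, each CES2 library lay above each Vector library. These were picked by small p, and the groups overlapped in all other members, so non-overlap held for 35.7% of the 28. Per library, the list's median relative to each gene's mean was -0.04, -0.56 and -1.05 log2 units in Vector and 0.76, 0.93 and 0.03 in CES2. Vector 1 and CES2 3 were thus closer to each other than to the other libraries of their groups. The number of members past over the list alone was 3 without CES2 1, 6 without Vector 3 or without CES2 2, 18 without Vector 1 and 20 without CES2 3.

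**Figure D1:**
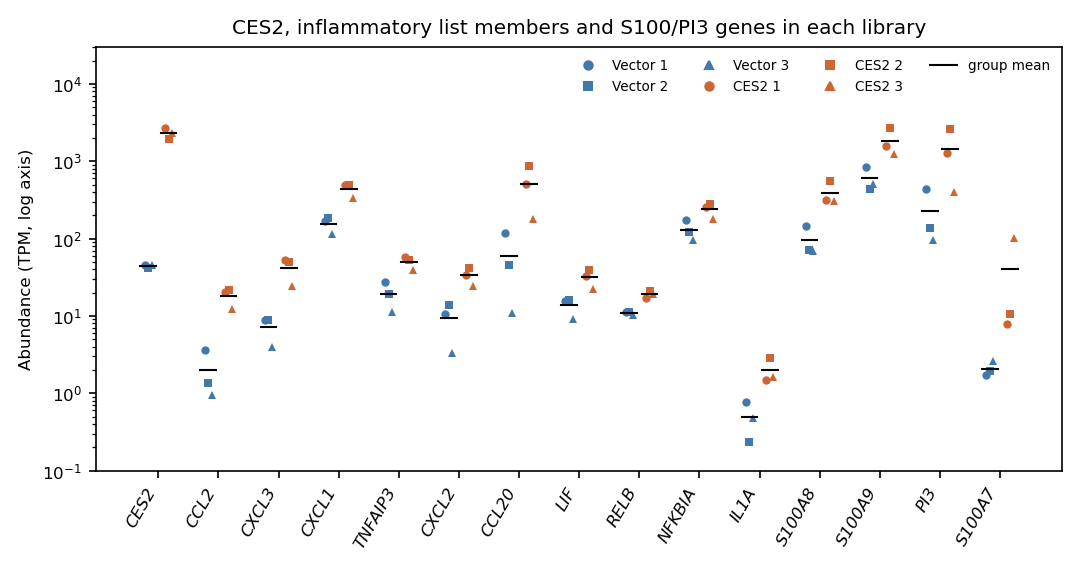
TPM of CES2, of the 10 inflammatory list members past the threshold adjusted over the list alone, and of S100A8, S100A9, PI3 and S100A7 in each library on a log axis. Points are libraries, with shapes for replicate numbers, and black lines are group means. CES2 lay at 41.9 to 45.6 TPM in Vector and 1929 to 2664 TPM in CES2, and the groups of PI3 overlapped.

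Interferon-stimulated genes were lower in CES2 as a list, at 36 of 38 tested members, with a median log2 fold change of -0.32 (camera adjusted p = 7.35e-12, adjusted p = 0.389 with an estimated correlation). None passed over all genes and 0 passed adjusted over the list alone. DDX60, an antiviral helicase, was at 46.4 ± 4.59 TPM in Vector and 28.1 ± 0.892 TPM in CES2 (SD, n = 3 each), a log2 fold change of -0.70. Log2 fold changes were -0.87 for SAMD9L, -1.35 for RSAD2, which encodes viperin, and -0.72 for SAMD9. Without Vector 2 the mean log2 fold change moved from -0.37 to -0.16 and the list no longer passed (adjusted p = 0.608).

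Keratinocyte differentiation genes were split. The list passed as higher (20 tested, 13 higher, camera adjusted p = 8.33e-04, adjusted p = 0.389 with an estimated correlation), with a mean log2 fold change of 0.33 and a median of 0.04. None passed over all genes and 4 were higher when adjusted over the list alone: S100A8 and S100A9, the subunits of calprotectin, PI3, the protease inhibitor elafin, and S100A7, psoriasin. S100A8 was at 95.9 ± 44.9 TPM in Vector and 391 ± 138 TPM in CES2 (SD, n = 3 each), a log2 fold change of 2.06. Log2 fold changes were 1.58 for S100A9, 2.60 for PI3 and 2.86 for S100A7. These 4 are alarmins and antimicrobial proteins that inflamed epithelium also makes. The mean of S100A7 in CES2 was drawn up by CES2 3, at 102 TPM against 7.91 and 10.7 TPM. The list no longer passed without Vector 2 (mean 0.18, adjusted p = 0.0573) or without CES2 3 (mean 0.20, adjusted p = 0.102), nor with library weights (mean 0.05, adjusted p = 0.266).

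Stress and redox lists passed as higher with small medians. Targets of NRF2, the oxidative stress regulator, were higher at 18 of 24 members (median 0.19, camera adjusted p = 1.64e-05, adjusted p = 0.665 with an estimated correlation), with log2 fold changes of 1.5 for AKR1C1, 1.23 for AKR1C2, 0.88 for AKR1C3 and 0.44 for GCLC. The AKR1C genes are near-identical neighbours on chromosome 10, so the values of each are uncertain where reads match more than 1 of them. ER stress genes were higher at 16 of 21 members (median 0.14, adjusted p = 2.51e-04, adjusted p = 0.433 with an estimated correlation), with CANX at 0.49, HERPUD1 at 0.42, CRELD2 at 0.33 and SYVN1 at -0.45. The mean of the ER stress list was 0.12, and it was 0.049 without Vector 2 (adjusted p = 0.0431), 0.078 without CES2 1 (adjusted p = 0.0194) and 0.19 without Vector 3 (adjusted p = 7.14e-04). Heat shock chaperones were higher at 12 of 15 members (median 0.11, adjusted p = 6.15e-04, adjusted p = 0.297 with an estimated correlation), with HSPA1A at 0.49, HSPA1B at 0.44, HSPE1 at 0.20 and HSPB1 at 0.14. HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. ATF4 targets were higher at 14 of 24 members (median 0.10, adjusted p = 0.0144, adjusted p = 0.584 with an estimated correlation), with NUPR1 at 0.71, CEBPB at 0.67, ATF3 at 0.51 and PSPH at -0.23. Xenobiotic metabolism genes were higher at 11 of 16 members (median 0.19, adjusted p = 0.00341, adjusted p = 0.665 with an estimated correlation), with CYP24A1 at 1.57, CYP1B1 at 0.56, ALDH1A3 at 0.39 and NQO1 at 0.26. The NRF2 list had a mean of 0.25, which was 0.012 without Vector 2, where it no longer passed (adjusted p = 0.506), and 0.46 without Vector 1. The xenobiotic list had a mean of 0.24, which was -0.07 without Vector 2 (adjusted p = 0.924), 0.13 without CES2 2 (adjusted p = 0.135) and 0.45 without Vector 1. The ATF4 list had a mean of 0.14 and no longer passed without Vector 2 (mean 0.042, adjusted p = 0.129), Vector 3 (mean 0.095, adjusted p = 0.764), CES2 1 (mean 0.084, adjusted p = 0.0908) or CES2 2 (mean 0.075, adjusted p = 0.0711), while the mean was 0.27 without Vector 1 and 0.25 without CES2 3. After quantile normalization the ATF4 mean was 0.16 but the list did not pass (adjusted p = 0.094). The heat shock list had a mean of 0.12, which was 0.033 without CES2 3 (adjusted p = 0.339), 0.067 without Vector 1 (adjusted p = 0.0403) and 0.23 without CES2 2.

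Energy and sterol metabolism lists also passed as higher. Oxidative phosphorylation genes were higher at 31 of 41 members (median 0.07, adjusted p = 3.01e-05, adjusted p = 0.131 with an estimated correlation), with NDUFA13 at 0.41, NDUFS7 at 0.40, COX7A2 at 0.23 and CYC1 at 0.22. The mean log2 fold change was 0.075 both for this list and for cholesterol synthesis genes, and 0.13 for both after median rescaling. Glycolytic genes were higher at 18 of 21 members (median 0.14, adjusted p = 1.63e-04, adjusted p = 0.665 with an estimated correlation), with GPI at 0.29, PFKP at 0.26, PFKL at 0.23 and ALDOA at 0.20. Cholesterol synthesis genes were higher at 18 of 24 members (median 0.07, adjusted p = 0.0203, adjusted p = 0.850 with an estimated correlation), with SC5D at 0.42, HSD17B7 at 0.30, LSS at 0.20 and DHCR7 at 0.16. Hypoxia response genes were higher at 14 of 21 members (median 0.06, adjusted p = 0.0447, adjusted p = 0.850 with an estimated correlation), with ANKRD37 at 0.54, HILPDA at 0.47, ADM at 0.46 and VEGFA at 0.33. Without CES2 1 the hypoxia list turned to a mean log2 fold change of -0.34 (adjusted p = 0.019), the glycolysis list to -0.05 (adjusted p = 0.575) and the cholesterol list to -0.02 (adjusted p = 0.428), against means of 0.10, 0.13 and 0.075 with all libraries. The hypoxia list also failed without Vector 2 (mean 0.037, adjusted p = 0.124), Vector 3 (mean 0.015, adjusted p = 0.764) or CES2 2 (mean -0.09, adjusted p = 0.743). The cholesterol list also failed without Vector 2 (mean -0.20, adjusted p = 0.608), Vector 3 (mean 0.069, adjusted p = 0.353) or CES2 2 (mean -0.04, adjusted p = 0.604). Without Vector 3 the oxidative phosphorylation (mean 0.042, adjusted p = 0.185) and glycolysis (mean 0.053, adjusted p = 0.386) lists did not pass. The hypoxia list passed as higher in 9 of 22 alternatives, and as lower without CES2 1. Its mean was not smaller after median rescaling (0.16, adjusted p = 0.128) or quantile normalization (0.17, adjusted p = 0.0821), nor was that of the cholesterol list after quantile normalization (0.077, adjusted p = 0.166), although none of these passed. Per library, the median of the cholesterol list relative to the gene means was 0.54, -0.61 and 0.011 in Vector and 0.21, 0.34 and -0.45 in CES2, and that of the hypoxia list 0.19, -0.12 and -0.15 in Vector and 0.76, 0.31 and -0.88 in CES2. Both lists loaded at percentile 100 of random lists on the first residual component, which Vector 1 and CES2 2 share across the groups.

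Replication-dependent histone genes were higher at 24 of 30 members (median 0.19, adjusted p = 3.04e-04, adjusted p = 0.665 with an estimated correlation), with HIST1H3C at 0.95, HIST1H4H at 0.58, HIST1H2BH at 0.50 and HIST1H3F at 0.49. Without CES2 3 the mean of this list was -0.08 (adjusted p = 0.686) and without Vector 1 it was -0.07 (adjusted p = 0.665), and the list loaded on the component shared by Vector 1 and CES2 2 at percentile 0 of random lists. Targets of YAP and TEAD, the effectors of Hippo signalling, were lower at 18 of 23 members (median -0.21, adjusted p = 0.0447, adjusted p = 0.665 with an estimated correlation), with RBMS3 at -0.91, NT5E at -0.42 and AMOTL2 at -0.40, while IGFBP3 was at 0.91. The mean of the YAP/TEAD list was -0.21, and without Vector 2 it was the same but the list no longer passed (mean -0.21, adjusted p = 0.307). It shrank and no longer passed without Vector 3 (mean -0.06, adjusted p = 0.341), CES2 1 (mean -0.13, adjusted p = 0.505) or CES2 2 (mean -0.14, adjusted p = 0.282), and was -0.35 without Vector 1 and -0.36 without CES2 3. Apart from CES2, none of the genes named in the stress, metabolic, histone and YAP/TEAD lists passed over all genes or over its list alone.

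**Figure D2:**
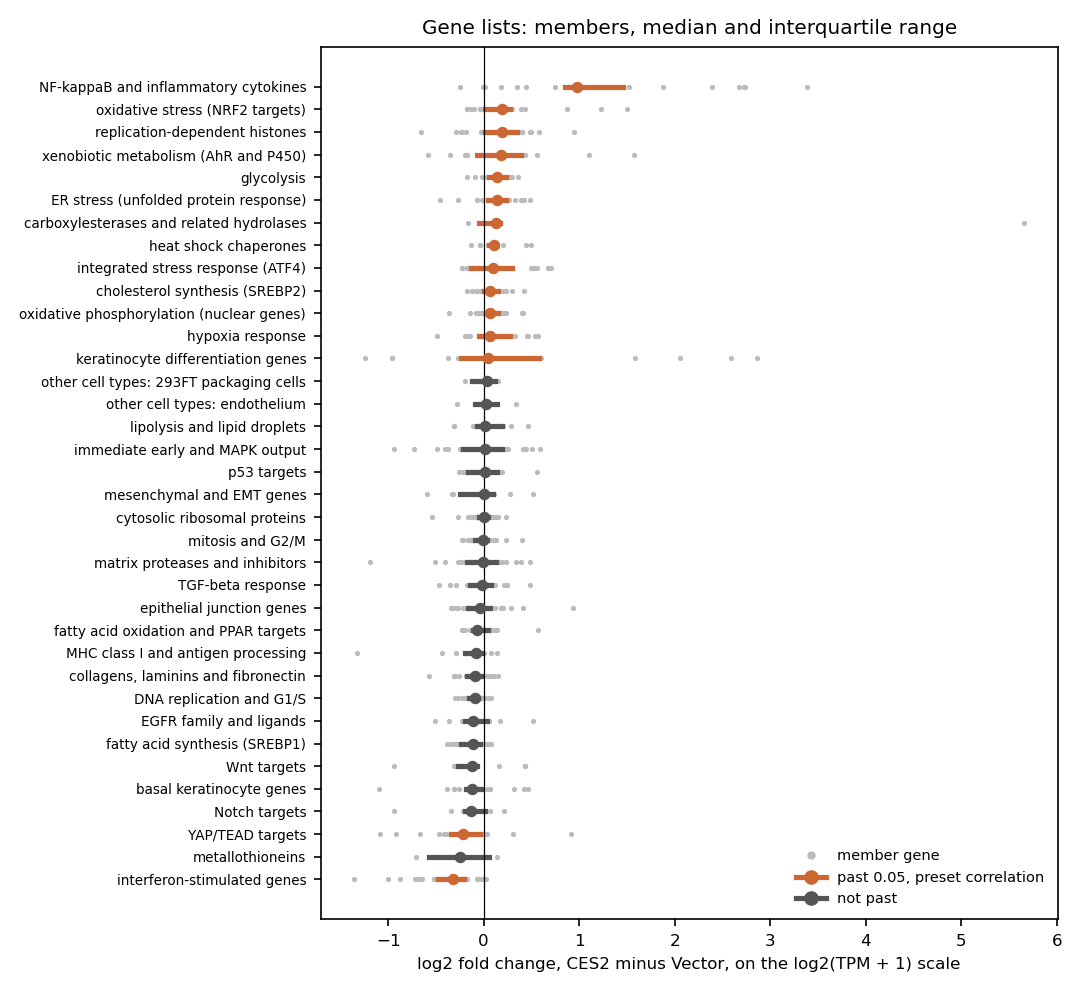
Log2 fold change (CES2 minus Vector, log2(TPM + 1) scale) of the members of each of the 36 tested lists. Grey points are genes, large points are medians and bars are interquartile ranges, coloured where camera with the preset correlation passed. The inflammatory list has a median of 0.98 and the interferon list one of -0.32.

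In all, 15 of 36 tested lists passed, 13 higher and 2 lower. Across genes the log2 fold change had a Spearman rho of 0.301 with GC content and -0.194 with transcript length. Only the inflammatory and interferon lists were compared with random lists matched on these. For the other lists that passed, most with small medians, a GC or length trend was not tested. With an estimated correlation 0 lists passed (lowest adjusted p = 0.131). The estimate was 0.414 for the inflammatory list, 0.279 for the interferon list, 0.536 for cholesterol synthesis and 0.793 for hypoxia, against the preset 0.01. It was -0.02 for oxidative phosphorylation. The fry test, which asks whether a list moves one way without comparing it with other genes, passed 1, the carboxylesterases. When data with no changed gene were simulated with the residual correlation of these libraries, a median of 11 lists and at most 17 passed. A count of 15 is within what such data gave. In the simulation the largest shared component fell on the groups at random. In the real libraries the groups' mean scores on the first component of genes outside the inflammatory list differed by only 0.042 SD. The simulated counts thus need not hold exactly for these libraries. Other splits of the 6 real libraries into 3 and 3 nonetheless passed 6 to 19 lists. Among them, Vector 1, CES2 1 and CES2 3 against the rest passed 12. The scores of these libraries on the first residual component, 0.52, 0.08 and -0.57, nearly cancel. Balance on that component thus did not by itself keep the list count low.

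The 21 other lists did not pass (adjusted p from 0.167 to 0.992). Among lipid lists, which relate to the enzyme's substrates, medians were 0.02 for lipolysis and lipid droplets, -0.06 for fatty acid oxidation and PPAR targets and -0.12 for fatty acid synthesis. Growth lists had medians of -0.09 for DNA replication, where 37 of 41 members were below 0 and the median of all tested genes was itself -0.057, -0.002 for mitosis, 0.014 for p53 targets and 0.004 for ribosomal proteins. Signalling lists had medians of 0.02 for immediate early genes, -0.11 for the EGFR family, -0.01 for the TGF-beta response, -0.12 for Wnt targets and -0.14 for Notch targets. Epithelial and matrix lists had medians of 0.01 for mesenchymal genes, -0.04 for epithelial junctions, -0.12 for basal keratinocyte genes, -0.004 for matrix proteases and -0.09 for collagens and laminins. The median was -0.08 for MHC class I genes and -0.25 for metallothioneins, of which 4 were tested. Mean and median had different signs in 4 lists (ribosomal proteins, immediate early genes, mesenchymal genes and 293FT markers). In the mitosis, TGF-beta, epithelial junction and matrix protease lists the test pointed higher although mean and median were below 0.

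Markers of other cell types did not separate the groups. The endothelial list (4 tested, median 0.02, adjusted p = 0.484) and the list for 293FT packaging cells (5 tested, median 0.04, adjusted p = 0.523) did not pass. Fibroblast and leukocyte lists had 1 and 2 tested members and were not tested: COL1A1 was at 6.80 TPM in Vector and 6.87 TPM in CES2, CD68 at 8.30 and 6.96 TPM and CORO1A at 9.59 and 10.6 TPM. Lists of mitochondrially encoded genes and small structural RNAs had 0 tested members.

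The libraries shared a difference that did not follow the groups. The first component of the residuals held 59.5% of residual variance, with scores of 0.52, -0.39 and -0.13 in Vector and 0.08, 0.49 and -0.57 in CES2. Vector 1 and CES2 2 stood at one end. TXNIP, a glucose-regulated gene named after its values were seen, was at 218 and 95.1 TPM in these 2 libraries and at 0.918 to 6.20 TPM in the other 4.

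**Figure D3:**
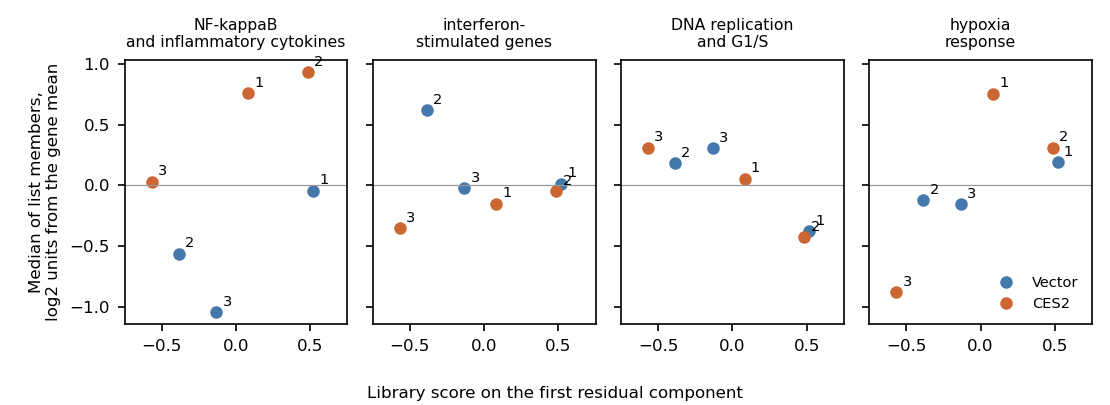
Median level of 4 gene lists in each library (log2 units from each gene's mean) against the library's score on the first residual component. Points are libraries, coloured by group and marked with the replicate number. Vector 1 and CES2 2 lie together at scores of 0.52 and 0.49, and the DNA replication list is lowest there.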

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

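The added fits (first residual component as a covariate, Vector 1 and CES2 2 left out together, blanks as missing) were chosen after the data were seen. CES2 kept its direction and passed in each alternative. Genes higher numbered 4 with library weights, 5 with the residual component (CES2, CCL2, PI3, S100A8 and S100A9) and 2 without Vector 1 and CES2 2, against 1. That component is orthogonal to the groups by construction and only lowers the residual spread, and the weights gave CES2 1 a weight of 6.86, so neither tests bias. Genes lower ranged from 0 to 1 when libraries were left out, with RTEL1-TNFRSF6B passing without CES2 3. Lists changed numbered 0 with an estimated correlation and 1 with fry, against 15. When libraries were left out they numbered from 10 (without Vector 2) to 19 (without Vector 1). Quantile normalization and an adjusted p under 0.01 each gave 11.

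The inflammatory list (mean 1.22, which the list test does not alter) no longer passed with an estimated correlation (adjusted p = 0.131). It did not pass by fry either (adjusted p = 0.402), which asks another question, whether the members move one way, and compares them with no other genes. It passed in the other 20 alternatives, with means from 0.94 to 1.54. All 20 used camera with the preset correlation, so they do not test that assumption, and both alternatives that changed it failed. Its members past adjusted over the list alone numbered 3 to 20 when libraries were left out, 3 at an adjusted p under 0.01, and 22 with library weights or with the residual component, against 10. The interferon list, with a mean of -0.37, did not pass with an estimated correlation (adjusted p = 0.389) or fry (adjusted p = 0.999), and its mean ranged from -0.47 to -0.16 when libraries were left out, not passing without Vector 2 (adjusted p = 0.608).

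Signs turned in some lists when libraries were left out: means ranged from -0.047 to 0.38 for glycolysis, -0.079 to 0.52 for histones, -0.07 to 0.45 for xenobiotic metabolism, -0.20 to 0.36 for cholesterol synthesis and -0.34 to 0.74 for hypoxia. With library weights histones were at -0.16 and xenobiotic metabolism at -0.003. Over all alternatives the highest means were 0.452 for glycolysis and 0.835 for hypoxia, above their leave-one-out ranges. Single genes turned too, none of them past the threshold: leave-one-out ranges were -0.20 to 0.061 for CMBL, -0.12 to 0.40 for CES4A, -0.21 to 0.75 for HSD17B7, -0.20 to 0.53 for LSS, -0.026 to 0.29 for HSPB1, -0.077 to 0.54 for HSPE1 and -0.026 to 1.12 for HIST1H4H. CMBL was at 0.011 with median rescaling, 0.005 with quantile normalization, 0.10 with library weights and 0.16 without Vector 1 and CES2 2. With library weights CES4A was at -0.026 and HSPB1 at -0.12. The cause was not tested. The hypoxia list also failed with a mean of at least 5 TPM (list mean 0.081, adjusted p = 0.0903), pseudocounts of 0.1 (0.094, adjusted p = 0.0672) and 0.01 (0.093, adjusted p = 0.0707) and without Vector 1 and CES2 2 (0.064, adjusted p = 0.12). YAP/TEAD targets kept their sign and passed in 11 of 22 alternatives, failing with quantile normalization (mean -0.15, adjusted p = 0.0624), no filter (-0.21, adjusted p = 0.0545), a mean of at least 5 TPM (-0.17, adjusted p = 0.163) and limma without the trend (-0.21, adjusted p = 0.051).

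With the replicate number as a block, 1 gene was higher and 0 were lower, 15 lists passed and 15 inflammatory members passed adjusted over the list alone. Deviations of same-numbered libraries correlated at 0.15, -0.52 and 0.38, within the range of -0.678 to 0.682 for libraries of different number. These values show no clear pairing by number, but so few cannot exclude it. TPM keeps no depth, so no result could be weighed by depth.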

Other observations

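Among genes outside the fixed lists, some of those with the smallest unadjusted p were chosen after their values were seen, and none passed over all genes (limma adjusted p = 1 for each). IL22RA2, a soluble decoy receptor for interleukin 22, was at 3.802, 3.796 and 3.67 TPM in Vector and 14.6, 10.8 and 8.50 TPM in CES2, a log2 fold change of 1.34 with a standard error of 0.26. ZC3H12A, an RNase that degrades cytokine messages, had a log2 fold change of 1.42, IFNGR1, an interferon gamma receptor subunit, one of 0.84 and TFRC, the transferrin receptor, one of 0.74. CTBP2, a transcriptional corepressor, was at 142, 139 and 158 TPM in Vector and 89.6, 49.8 and 49.7 TPM in CES2, a log2 fold change of -1.26. YTHDF2, a reader of methylated RNA, had a log2 fold change of -0.99. The listed transcript had only 354 bases for TFRC and 864 bases for YTHDF2, so these values may not stand for the whole gene. IL22RA2 (up to 137173648) and IFNGR1 (from 137197484) are close on the minus strand of chromosome 6 and may not be separate observations. Within the keratinocyte differentiation list, KRT13, a keratin of the differentiating oral mucosa that falls outside the naming rule and was chosen after its values were seen, had means of 1596 TPM in Vector and 884 TPM in CES2, a log2 fold change of -0.96 that did not pass adjusted over the list alone (adjusted p = 0.114). Across genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.301 with GC content and -0.194 with transcript length.

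The tests of the shared component against the inflammatory list, of Vector 2, of GC content and growth state for the component, and the counts of genes in other splits were chosen after the result was seen.

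The higher inflammatory list is the pattern most open to follow-up. Its median lay at percentile 100 of 10000 random lists matched on GC content, length and expression, which argues against a GC or length trend. Without the CXCL and SAA genes, which have close relatives, the median of the remaining 22 members was 0.94, which argues against reads shared between relatives. The groups' mean scores on the first component of all other genes differed by only 0.042 SD, so the structure shared by Vector 1 and CES2 2 does not account for the whole group difference, although the list does load on that component at percentile 100. A response to CES2 stays open as a hypothesis, untested, as do culture or transduction differences between the groups, and the split of Vector 1, CES2 1 and CES2 2 against the rest gave a mean of -1.21, as large as the real 1.22.

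The lower interferon list lay at percentile 0 of matched random lists, which argues against GC content or length. Vector 2 was the library with the highest level of the list, at 0.62 log2 units above the gene means against -0.35 to 0.02 elsewhere. Without Vector 2 the median was -0.12, between the bounds of -0.1 and -0.15 set for this test. The test thus could not tell a contribution of that 1 library alone from a group difference. The median of all tested genes without Vector 2, looked up after that value was seen, was also -0.12. By the median, no decrease particular to the list was therefore seen without Vector 2. In 6 of the 38 members each CES2 library lay below each Vector library, so a difference in some members stays possible. The split of Vector 1, Vector 2 and CES2 2 against the rest gave a mean of -0.353, near the real -0.369. That of Vector 1, CES2 1 and CES2 3 gave 0.355, and the remaining splits were smaller in size. A response to CES2 was not tested separately.

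The component shared by Vector 1 and CES2 2 had its largest Spearman rho across genes, which are not independent replicates, at 0.058 with GC content, which argues against GC content or length. Without overlapping and readthrough genes it still held 60.7% of residual variance, so reads moved between overlapping genes do not account for it. DNA replication genes loaded at percentile 0 of random lists and YAP/TEAD targets at percentile 0.81, just short of the bound set for that list, while mitosis genes, at percentile 36.2, lay within random lists, and cholesterol, hypoxia and matrix protease lists were at 100, so growth state of the cultures stays open. No biological explanation from the design was tested, since the component crosses the groups.

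Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes, the larger direction of each other split was counted, because swapping the sides of a split turns higher into lower. Counted so, 4 of 10 splits gave as many genes as the real 1 higher (highest other 62). For lists 3 of 10 splits gave as many as the real 15 (highest other 19). The split of Vector 1, CES2 1 and CES2 2 against the rest called 99 genes, which points to a structure of the samples. For genes lower the real count was 0, so that 10 of 10 splits gave as many (highest other 62) was fixed by that count and tests nothing.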
